A study of Arabidopsis thaliana with 72 samples.

How the data were processed

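RNA was sequenced from shoots and roots of 14-day-old Arabidopsis thaliana seedlings given citral (202 µM per the series design), 0.1% ethanol or nothing. RNA was isolated with a column kit and libraries were made with a TruSeq RNA kit, per the labels' protocols. The treatment protocol in the labels names t-chalcone at 21 µM, 7 h into a photoperiod of 16 h of light and 8 h of dark, while the agent labels, the series design and the title name citral; the agent labels were followed. Each sample's group came from its organ, agent and time labels, which gave 24 groups of 3 libraries. Nothing says that the replicates are separate plates.

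The authors deposited 1 table of 22122 loci by 72 libraries, whose values are whole numbers of 1 or more and were treated as a score. A scaling by TMM is named with the table, per the file name, and the genome build is TAIR10, per the submitters' processing notes. The aligner, the counting tool and the use of strand are not given in the sources used here. Columns matched samples by title, and no other column of samples was present (0 not used). Column totals ran from 129632 to 23112599, so the deposited values are not divided by library size. In each column the values up to 150 sat on a grid of whole reads times 1 factor per library, rounded, with values under 1 set to 1. The factor with the highest likelihood on that grid ranged from 0.6655 to 1.311, 5 libraries had a factor of 1, and at least 98.7% of the values of each library lay on its grid. Reads were recovered by dividing by the factor, and a value of 1 at the floor was taken as 0.5 read.

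Recovered reads per library ranged from 0.183 to 20.6 M. The 30 citral libraries held 1.58 to 3.59 M (median 3.43) and the 38 control libraries of 0.5 M or more at least 1.905 M, with a median of 11.4 over all 42 controls. At these depths a locus at 1 CPM rests on 1.58 to 3.59 reads in citral libraries, and intervals and floors cover counting error only. Means ± SD in recovered reads per M (CPM) leave out the 4 libraries under 0.5 M, and the tests keep them with their weights. Over the 72 pairs of replicates the variance between libraries was at least 1.29 times the sampling noise (median 5.68), 0 pairs were identical, and all libraries were counted as separate samples.

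The test written before the data were examined was limma-trend on log2 values with 1 common factor for all libraries and a pseudocount of 0.5 CPM. It presumed values comparable between libraries, which the totals contradict, so the test used was chosen after the table was seen. It was limma's voom with library quality weights on the recovered reads, scaled by TMM factors computed here (30% of log ratios and 5% of abundances trimmed, over loci averaging 10 CPM or more). Each organ was fitted as 1 model of 12 group means over its 36 libraries, with moderated tests and a robust prior. Loci needed 1 CPM in at least 3 libraries, which left 19607 in shoots and 20144 in roots. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The difference of the citral response between organs was tested over the 5 times by a limma F test on all 72 libraries. No 2 of the 12 comparisons share libraries except through the common variance model.

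In total 22 gene lists were written before the data were examined: single-stranded DNA-binding proteins, detoxification, heat shock and protein folding, oxidative stress, jasmonate, salicylic acid, early stress and touch, abscisic acid and drought, auxin, ethylene, microtubules, cell cycle and DNA replication, DNA damage response, unfolded protein response, photosynthesis, root tissue, phenylpropanoids and flavonoids, hypoxia, carbon starvation and darkness, circadian clock, isoprenoid synthesis, and sulfate assimilation and glutathione. They were tested with limma's camera at its preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over 220 tests for citral and 44 for the 0 h comparisons. Member counts are given over all genes tested and adjusted over the list alone. Of 465 list genes 4 were not in the table. In 131 of the 264 tests the list passed with the preset correlation, and in 31 also with the estimated one.

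Genes named in the text followed a rule written before the data were examined. It took the 5 largest increases and decreases of each citral comparison among called genes whose groups do not overlap and whose mean is at least 5 CPM in the higher group. It also took up to 4 called members of each list and organ at the time with most calls, all single-stranded DNA-binding proteins, the 5 genes per direction with the smallest p for the organ difference, and the 5 largest changes per organ at 0 h. Last came CCA1, LHY, TOC1, ELF4, RBCS1A, LHCB3, COBL9 and CASP1 as checks of the labels. Genes of the first 3 parts could be given at other times and in the other organ. FZF is outside the rule. Names and overlaps came from a TAIR10.1 annotation, in which 21979 of the loci were found, and no coordinates are given because the builds may differ.

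The method was tested on negative binomial reads simulated with the real means, spreads, depths and scaling factors, with 200 genes changed in each comparison. These were raised and lowered in equal number, while 4023 to 9828 genes were called in the real citral comparisons. The scaling and the share of false calls were thus not tested with so many genes changed. In shoots at 1 h, over 19317 loci, 68% of genes changed 2-fold and 92% of those changed 4-fold were recovered, and 5.9% of the called genes were false. In roots at 1 h, over 19960 loci, these values were 66%, 89% and 4.3%. For the difference between organs, with 200 genes changed in roots at 3 h alone over 20881 loci, 33% and 62% were recovered and 12.8% were false. Of 100 simulated lists without a shift 0 were called by camera in the set for shoots at 3 h. Genes were simulated independently of each other, so false calls from correlation within real lists were not tested. The estimated correlation in the test of organs reached 0.584 (carbon starvation and darkness).

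Alternatives written before the data were examined were other pseudocounts (0.1 and 2), no filter or 5 CPM, a fit of the compared groups alone, quantile normalization, centring on medians, limma without weights, trend or robust prior, and each library left out in turn. Added later were limma-trend per library at 0.5, the first planned test with 1 common factor, no library weights, the authors' scaling factors, the floor as 0 or 1 read, leaving out the 4 shallow libraries, and thinning to 1.5 M reads. Versions were limma 3.58.1, statmod 1.5.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.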

Results

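Gene expression was measured by RNA sequencing in shoots and roots of Arabidopsis thaliana seedlings grown on agar for 14 days. Citral, the mixture of the monoterpene aldehydes geranial and neral that gives lemongrass oil its scent, was applied at 202 µM, and plants given 0.1% ethanol served as controls at 1, 3, 6, 12 and 24 h. Untreated and ethanol plants were also sampled at 0 h. The 24 groups held 3 libraries each, 72 libraries in all. The concentration and the compound are those of the series design and the agent labels. The treatment protocol attached to the same samples instead names t-chalcone at 21 µM, and this conflict was not settled by the sources used here.

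Reads per library, recovered from the deposited values, ranged from 0.183 to 20.6 M. The 30 citral libraries held 1.58 to 3.59 M reads (median 3.43), and the median of the 42 control libraries was 11.4 M. In 4 control libraries there were fewer than 0.5 M reads: 0.255 in root ethanol 0 h replicate 1, 0.183 in root ethanol 3 h replicate 1, 0.326 in shoot ethanol 12 h replicate 2 and 0.360 in shoot ethanol 24 h replicate 3. Levels are given in counts per M recovered reads (CPM) as mean ± SD without these 4 libraries. Changes are log2 ratios ± SE from the limma fit, with n = 3 libraries per group, and every change called a rise or a fall had a Benjamini-Hochberg adjusted p under 0.05. Nothing in the labels says that replicates came from separate plates, so p-values measure the spread between these samples, which may be technical. The 22 gene lists, the 12 comparisons and the rule for the genes named were fixed before the data were examined; the test planned for them was replaced after the table was seen.

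The organ labels were checked with marker genes. In untreated plants RBCS1A (AT1G67090), the small subunit of Rubisco, stood at 9559 ± 668 in shoots and 25.5 ± 8.17 in roots (n = 3). COBL9 (AT5G49270), which is needed for root hair growth, stood at 0.213 ± 0.124 in shoots and 19.0 ± 1.71 in roots, and CASP1 (AT2G36100), of the Casparian strip, at 0.868 ± 0.273 and 98.0 ± 7.22. The hours were checked with clock genes. LHY (AT1G01060) and CCA1 (AT2G46830), which peak around dawn, stood at 721 ± 80.2 and 612 ± 38.4 in shoots after 12 h of ethanol (n = 2), and at 426 ± 29.2 and 402 ± 16.1 after 24 h. At 0 h, 1 day before the 24 h samples by the labels, ethanol shoots held 16.7 ± 2.05 and 49.5 ± 3.52. The root mean square log2 distance over 16 clock genes between the ethanol groups of 0 and 24 h was 2.40 in shoots and 1.98 in roots, against 0.82 and 0.68 from the 0 h groups to the ethanol groups of 3 h.

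**Figure D1:**
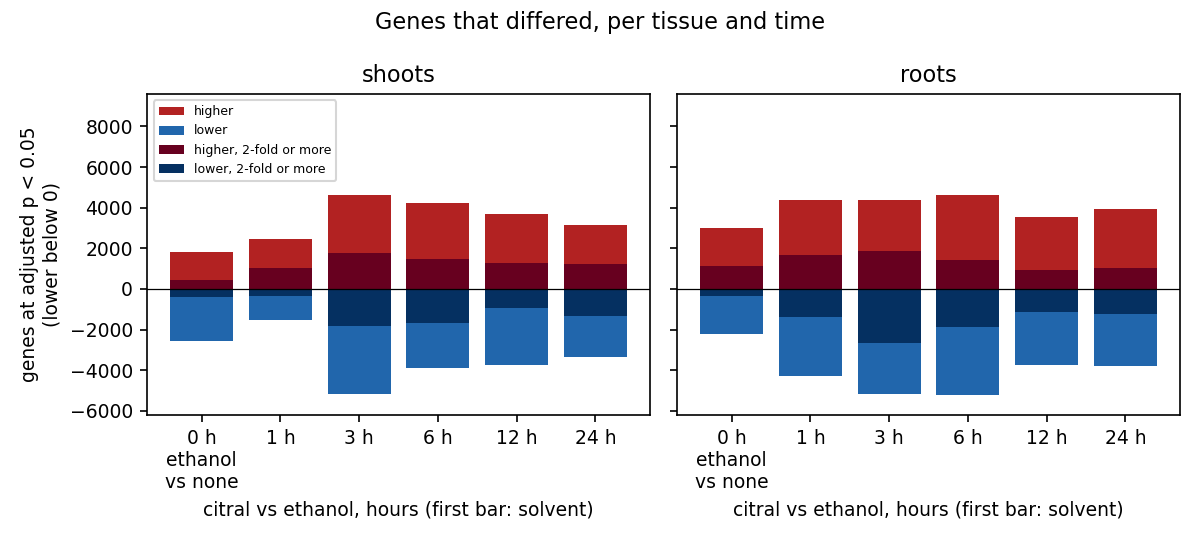
Genes that differed at adjusted p under 0.05, higher above 0 and lower below 0, for ethanol against untreated plants at 0 h and citral against ethanol at 1 to 24 h, with genes of 2-fold or more in the darker shade. In shoots the count went from 4023 at 1 h to 9804 at 3 h, and in roots it was highest at 6 h with 9828. Without library weights the root count was highest at 3 h, with 9629 against 8413 at 6 h.

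The first comparison asked which genes differed in shoots after 1 h of citral. The largest rises were in genes of detoxification. CYP81D11 (AT3G28740), a cytochrome P450 of the xenobiotic response, rose by 8.74 ± 0.49 on the log2 scale (1606 ± 117 against 3.78 ± 0.279 CPM, adjusted p = 2.1e-13). GSTU24 (AT1G17170), a glutathione transferase, rose by 8.07 ± 0.59 (957 ± 139 against 3.61 ± 0.269), and the oxidoreductase gene AT5G22140 by 8.17 ± 0.69. In the detoxification list 33 of 46 members (33 adjusted over the list alone) rose and 0 fell, with a median of 2.53 (adjusted p = 1.91e-33, adjusted p = 0.0158 with an estimated correlation). Of the photosynthesis list 24 of 29 members (25 adjusted over the list alone) fell, median -0.72 (adjusted p = 3.17e-18, adjusted p = 0.0385 with an estimated correlation). LHCB3 (AT5G54270), a light-harvesting protein of photosystem II, fell by 1.5 on the log2 scale (732 ± 179.5 against 2139 ± 255). With ethanol alone the light-harvesting gene LHCB1.1 (AT1G29920) ran from 5070 to 6338 CPM over libraries at 0 h and 1248 to 1417 at 1 h.

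Several lists moved less evenly in these shoots. The heat shock and protein folding list had 14 of 25 members (16 adjusted over the list alone) rising, median 2.48 (adjusted p = 1.07e-09, adjusted p = 0.225 with an estimated correlation). Of the hypoxia list 10 of 14 members (11 adjusted over the list alone) fell and 2 rose (adjusted p = 0.000186, adjusted p = 0.246 with an estimated correlation). Its members HRA1 (AT3G10040) and HRE2 (AT2G47520), both regulators of the low-oxygen response, changed by -2.32 ± 0.32 and 2.13 ± 0.66. In the ethylene list 4 of 18 members rose and 5 fell (4 and 5 adjusted over the list alone), with ERF1A (AT4G17500) at 1.37 ± 0.39 and ERF105 (AT5G51190) at -2.47 ± 0.58, and the list as a whole did not pass (adjusted p = 0.627). Of the genes with the largest falls, AT5G62360, annotated as a pectin methylesterase inhibitor, changed by -3.08 ± 0.35 and WRKY53 (AT4G23810), a senescence regulator, by -3.17 ± 0.90. In all, 2471 genes were higher and 1552 lower among 19607 tested, 1038 and 329 of them by 2-fold or more. The 2 groups did not overlap in 36% of genes, against 10% by chance. Here and below, values at the floor entered as 0.5 read over the library's size. Loci at the floor in all 6 libraries can thus separate by depth alone, and the 10% holds only for libraries alike in depth. The share of higher genes was 61.4%, 35.4% with the authors' scaling factors and 46.4% after quantile normalization. Without library weights 1526 genes passed, and 2578 passed without citral replicate 3, where the calls of HRE2, ERF1A and WRKY53 were lost; that of ERF105 was lost with limma-trend at a pseudocount of 0.5.

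After 3 h of citral, genes of detoxification and sulfate assimilation rose in shoots. BGLU28 (AT2G44460), a beta-glucosidase, rose by 8.96 ± 0.98 (290.2 ± 54.8 against 0.589 ± 0.178, adjusted p = 3.04e-08), ABCG40 (AT1G15520), a transporter of the plasma membrane that imports abscisic acid, by 6.78 ± 0.42 and the glucosyltransferase UGT74E2 (AT1G05680) by 6.48 ± 0.63. The cytochrome P450 gene CYP89A6 (AT1G64940) rose by 6.48 ± 0.53, and GSTU24 reached 2212 ± 159 against 27.4 ± 11.4. Of the detoxification list 41 of 46 members (41 adjusted over the list alone) rose and 0 fell, median 3.34 (adjusted p = 3.07e-30, adjusted p = 0.0215 with an estimated correlation). Of the sulfate assimilation and glutathione list 11 of 11 members (11 adjusted over the list alone) rose, median 2.41 (adjusted p = 6.03e-12, adjusted p = 0.0231 with an estimated correlation). Its members APR3 (AT4G21990), which reduces activated sulfate, and SERAT2;1 (AT1G55920), which makes the cysteine precursor, rose by 4.72 ± 0.32 and 3.26 ± 0.16. SDI1 (AT5G48850) and LSU1 (AT3G49580), markers of sulfur limitation, rose by 5.85 ± 0.48 and 5.55 ± 0.49.

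Stress hormone and redox genes rose in part. In the oxidative stress list 12 of 21 members (12 adjusted over the list alone) rose and 2 fell (adjusted p = 2.55e-05, adjusted p = 0.217 with an estimated correlation), with the kinase OXI1 (AT3G25250) at 5.75 ± 0.52, the glutathione peroxidase GPX6 (AT4G11600) at 3.77 ± 0.19 and the zinc finger protein ZAT12 (AT5G59820) at 3.66 ± 0.42. Of the jasmonate list 11 of 25 members (11 adjusted over the list alone) rose (adjusted p = 0.0106, adjusted p = 0.604 with an estimated correlation), among them the synthesis genes LOX2 (AT3G45140) (2.67 ± 0.29) and AOC2 (AT3G25770) (2.57 ± 0.21). Of the abscisic acid and drought list 15 of 22 members (15 adjusted over the list alone) rose (adjusted p = 5.34e-05, adjusted p = 0.104 with an estimated correlation), among them the phosphatases HAI1 (AT5G59220) (3.64 ± 0.50) and ABI2 (AT5G57050) (2.14 ± 0.14), which restrain this hormone's signal. The ethylene list went both ways, 6 of 18 higher and 6 lower, the same numbers adjusted over the list alone, with ERF1 (AT3G23240) at 2.14 ± 0.50 and the synthase ACS8 (AT4G37770) at -1.93 ± 0.65 (adjusted p = 0.868).

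Cell cycle and auxin genes of these shoots fell for the most part. Of the cell cycle and DNA replication list 23 of 30 members (23 adjusted over the list alone) fell and 0 rose (adjusted p = 1.87e-05, adjusted p = 0.266 with an estimated correlation). The cyclins CYCA2;3 (AT1G15570) and CYCD3;1 (AT4G34160) changed by -1.85 ± 0.26 and -1.26 ± 0.18, and CDC6 (AT2G29680), which licenses replication origins, by -1.80 ± 0.29. Of the auxin list 13 of 18 members (14 adjusted over the list alone) fell (adjusted p = 0.00219, adjusted p = 0.247 with an estimated correlation), with the influx carrier AUX1 (AT2G38120) at -2.61 ± 0.16 and the repressor IAA14 (AT4G14550) at -2.09 ± 0.34, while GH3.3 (AT2G23170), which conjugates auxin, rose by 3.07 ± 0.21. The expansin EXPA8 (AT2G40610) changed by -4.05 ± 0.55. The DNA damage response list did not pass (adjusted p = 0.104), with 1 of 17 members higher and 6 lower, the same numbers adjusted over the list alone; the transcription factor NAC044 (AT3G01600) changed by 1.88 ± 0.44 and the ADP-ribose polymerase PARP1 (AT2G31320) by -1.30 ± 0.18. Of the clock genes ELF4 (AT2G40080) and LUX (AT3G46640), of the evening complex, rose by 3.93 ± 0.28 and 2.43 ± 0.13, and RVE1 (AT5G17300) fell by 2.27 on the log2 scale. The clock genes of these libraries lay 2.01 from their own ethanol group and 1.25 from the ethanol group of 6 h. In all, 4631 genes were higher and 5173 lower, 1771 and 1842 by 2-fold or more, and the groups did not overlap in 57.7% of genes (chance 10%). The share of higher genes was 47.2%, and 32.8% with the authors' scaling factors. Without library weights 4579 genes passed. The calls of ERF1, CYCD3;1, NAC044 and PARP1 were lost with limma-trend at a pseudocount of 0.1, and that of ACS8 without citral replicate 2.

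At 6 h light-harvesting genes fell in shoots. LHCB2.3 (AT3G27690), LHCB1.1 (AT1G29920) and LHCB1.4 (AT2G34430) changed by -5.14 ± 0.39, -4.18 ± 0.25 and -4.43 ± 0.32 (LHCB1.4 119.5 ± 56.9 against 2486 ± 616, adjusted p = 2.54e-11). With ethanol alone LHCB1.1 ran from 4233 to 5113 CPM over libraries at 3 h, 1194 to 1510 at 6 h and 5268 to 6153 at 12 h. Its level in the controls thus moved back and forth between adjacent times. Of the photosynthesis list 28 of 29 members (28 adjusted over the list alone) fell and 0 rose, median -1.70 (adjusted p = 1.02e-28, adjusted p = 0.0114 with an estimated correlation). ABCG40 rose by 7.12 ± 0.61, the beta-glucosidase BGLU30 (AT3G60140) by 6.71 ± 0.47 and AT3G59930, annotated as defensin-like, by 7.14 ± 0.84. Of the detoxification list 40 of 46 members (42 adjusted over the list alone) rose, median 3.48 (adjusted p = 1.91e-33, adjusted p = 0.0158 with an estimated correlation).

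The microtubule list had 16 of 20 members (17 adjusted over the list alone) falling and 1 rising, median -0.65 (adjusted p = 3.28e-08, adjusted p = 0.0676 with an estimated correlation), with the tubulins TUB1 (AT1G75780) at -2.42 ± 0.31, TUB5 (AT1G20010) at -2.10 ± 0.11 and TUA2 (AT1G50010) at -1.28 ± 0.13. Of the heat shock list 23 of 25 members (23 adjusted over the list alone) rose, median 3.06 (adjusted p = 9.09e-10, adjusted p = 0.224 with an estimated correlation), and HSP17.6A (AT5G12030), a small heat shock protein, changed by 5.13 ± 1.07 with levels of 42.2 ± 46.3 against 0.985 ± 0.922. The unfolded protein response list had 14 of 16 members (15 adjusted over the list alone) rising (adjusted p = 7e-06, adjusted p = 0.235 with an estimated correlation), among them the chaperones BIP2 (AT5G42020) (1.48 ± 0.22) and BIP3 (AT1G09080) (3.28 ± 0.89). Auxin genes fell in 14 of 18 members (14 adjusted over the list alone), median -1.63 (adjusted p = 4.85e-06, adjusted p = 0.0709 with an estimated correlation). The isoprenoid synthesis list went both ways, 3 of 16 higher and 7 lower, the same numbers adjusted over the list alone (adjusted p = 0.215): MCT (AT2G02500), of the plastid pathway, and the farnesyl diphosphate synthase FPS1 (AT5G47770) changed by -1.04 ± 0.13 and -0.91 ± 0.13, and the isomerase IPP2 (AT3G02780) by 0.61 ± 0.10. In all, 4232 genes were higher and 3898 lower, 1452 and 1677 by 2-fold or more, and 50.4% did not overlap (chance 10%). The share of higher genes was 52.1%, and 33.4% with the authors' scaling factors. Without library weights 3998 genes passed and the calls of MCT and FPS1 were lost; that of BIP2 was lost with limma-trend and that of HSP17.6A in a fit of the compared groups alone.

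At 12 h clock genes differed in shoots. LHY fell by 3.91 on the log2 scale (47.5 ± 8.46 against 721 ± 80.2, n = 3 and 2, adjusted p = 9.76e-17), and THI2.2 (AT5G36910), a thionin, changed by -3.97 ± 0.34. The 16 clock genes of the citral group lay 2.24 from their own ethanol group and 0.56 from the untreated group of 0 h. The clock list itself did not pass, with 8 higher and 6 lower of 16 (9 and 6 adjusted over the list alone, adjusted p = 0.727). Of the detoxification list 33 of 46 members (33 adjusted over the list alone) rose and 2 fell, median 1.48 (adjusted p = 2.22e-14, adjusted p = 0.128 with an estimated correlation), with GSTU24 at 2.93 ± 0.41. Of the salicylic acid list 10 of 19 members (11 adjusted over the list alone) rose (adjusted p = 0.000226, adjusted p = 0.323 with an estimated correlation), among them the pathogenesis-related genes PR5 (AT1G75040) (2.34 ± 0.47) and PR2 (AT3G57260) (4.5 ± 1.52). Of the phenylpropanoid and flavonoid list 10 of 15 members (10 adjusted over the list alone) fell and 1 rose (adjusted p = 0.000626, adjusted p = 0.266 with an estimated correlation): CHS (AT5G13930), the entry enzyme of flavonoid synthesis, changed by -3.01 ± 0.74, F3H (AT3G51240) by -1.94 ± 0.41 and DFR (AT5G42800) by -3.24 ± 1.00. In all, 3706 genes were higher and 3729 lower, 1268 and 948 by 2-fold or more, and 29.0% did not overlap (chance 10%). Ethanol replicate 2 was at the floor in 73.9% of loci and held 0.525% mitochondrial reads, against 0.0017% and 0.0018% in the other ethanol libraries. The count of 7435 was 3279 without library weights, 1015 without ethanol replicate 1 and 798 without ethanol replicate 3. Without either of them the calls of GSTU24, PR2, PR5, CHS and DFR were lost, and without replicate 3 that of F3H.

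At 24 h genes of carbon starvation and darkness rose in shoots. BGLU30, also known as a dark-induced gene, rose by 4.75 ± 0.50 (161 ± 10.5 against 5.32 ± 3.56, n = 3 and 2, adjusted p = 2.69e-08), SEN1 (AT4G35770), a senescence marker, by 3.01 ± 0.44, and BCAT2 (AT1G10070) and IVD (AT3G45300), which break down branched-chain amino acids, by 3.37 ± 0.71 and 2.23 ± 0.29. Of this list 11 of 12 members (11 adjusted over the list alone) rose, median 1.80 (adjusted p = 1.5e-08, adjusted p = 0.128 with an estimated correlation). GSTU24 rose by 2.89 ± 0.50, and of the detoxification list 33 of 46 members (33 adjusted over the list alone) rose (adjusted p = 1.06e-13, adjusted p = 0.131 with an estimated correlation). Of the heat shock list 19 of 25 members (20 adjusted over the list alone) rose (adjusted p = 2.03e-06, adjusted p = 0.337 with an estimated correlation). The iron reductase FRO2 (AT1G01580) changed by -4.39 ± 1.39, from 23.4 ± 0.615 with ethanol, and the root genes COBL9 and CASP1 stood at 0.584 ± 0.433 and 2.52 ± 1.88 with citral and 2.63 ± 1.03 and 4.91 ± 0.605 with ethanol in these shoots. CHS changed by -3.20 ± 0.71, with 10 of 15 members (10 adjusted over the list alone) of its list falling (adjusted p = 0.000593, adjusted p = 0.266 with an estimated correlation). The clock genes of these libraries lay 2.26 from their own ethanol group and 0.67 from the ethanol group of 3 h. In all, 3139 genes were higher and 3350 lower, 1238 and 1346 by 2-fold or more, and 38.1% did not overlap (chance 10%). The count of 6489 was 2693 without library weights, 3411 without citral replicate 2, and 3311 and 3742 without ethanol replicates 1 and 2, where the calls of FRO2 and BCAT2 were lost.

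**Figure D2:**
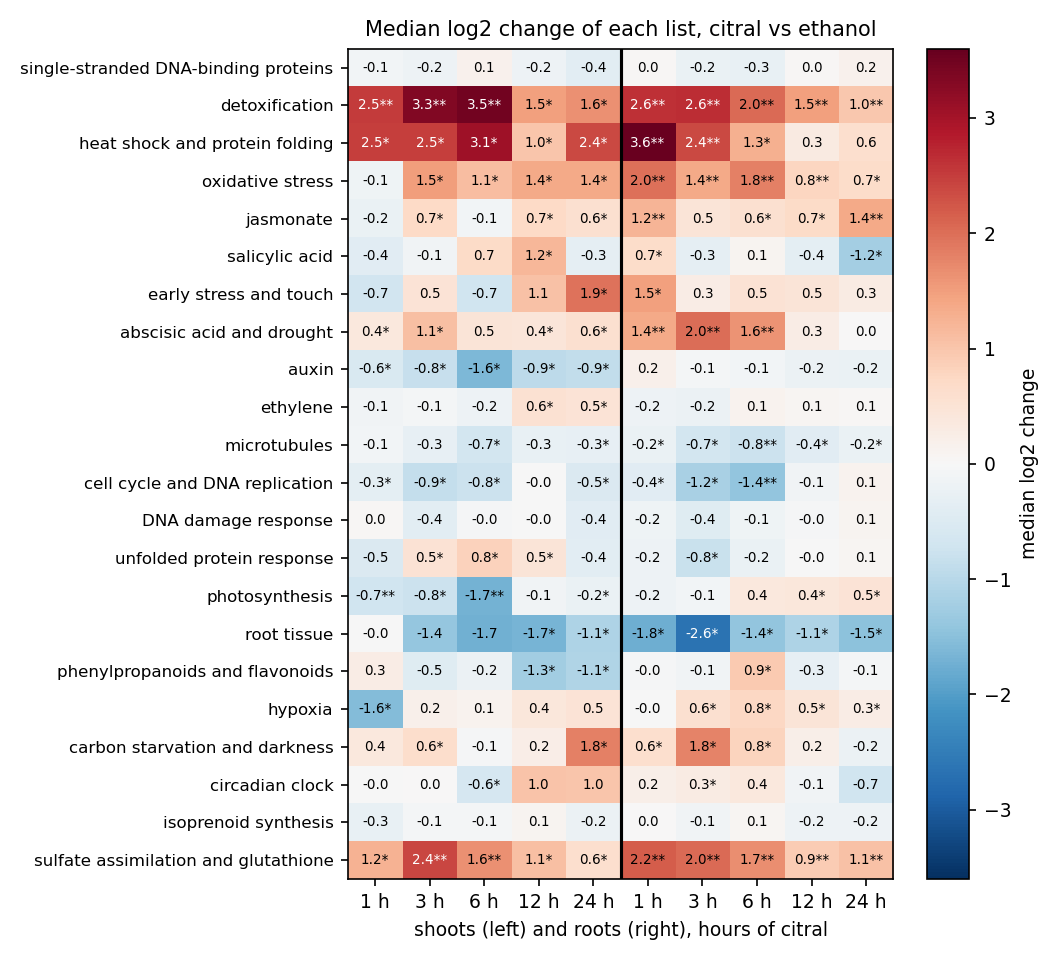
Median log2 change, citral against ethanol, of the measured members of each of the 22 gene lists at 5 times in shoots (left) and roots (right); 1 star marks adjusted p under 0.05 with the preset correlation, and 2 stars also with an estimated correlation. The highest median, 3.57, is that of the heat shock list in roots at 1 h, and the lowest, -2.65, that of the root tissue list in roots at 3 h.

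Roots responded to 1 h of citral with genes of detoxification and heat shock. ABCG40 rose by 8.59 ± 0.29 (801 ± 214 against 2.57 ± 0.75, adjusted p = 3.49e-20), DOGT1 (AT2G36800), a glucosyltransferase that acts on fungal toxins and brassinosteroids, by 7.41 ± 0.42, CYP81D11 by 4.79 ± 0.08 and GSTU24 by 4.64 ± 0.08. All 25 members of the heat shock and protein folding list rose (25 adjusted over the list alone), median 3.57 (adjusted p = 3.69e-21, adjusted p = 0.00746 with an estimated correlation), with the small heat shock proteins HSP17.6A at 6.02 ± 0.35 and HSP17.4 (AT3G46230) at 6.01 ± 0.33. Of the detoxification list 39 of 47 members (39 adjusted over the list alone) rose and 2 fell, median 2.62 (adjusted p = 1.81e-35, adjusted p = 0.000345 with an estimated correlation). Of the oxidative stress list 16 of 22 members (16 adjusted over the list alone) rose (adjusted p = 1.33e-09, adjusted p = 0.00315 with an estimated correlation), among them the transcription factors RRTF1 (AT4G34410) (4.66 ± 0.32) and WRKY75 (AT5G13080) (3.96 ± 0.09) and ZAT12 (3.17 ± 0.18). Of the sulfate list 10 of 11 members (10 adjusted over the list alone) rose, median 2.18 (adjusted p = 7.48e-12, adjusted p = 0.0114 with an estimated correlation).

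Hormone and touch genes of roots also moved at 1 h. Of the jasmonate list 18 of 23 members (18 adjusted over the list alone) rose (adjusted p = 2.9e-08, adjusted p = 0.0176 with an estimated correlation), with CYP94B3 (AT3G48520), which inactivates the hormone, at 3.29 ± 0.10 and the repressors JAZ8 (AT1G30135) and JAZ7 (AT2G34600) at 2.7 ± 0.37 and 2.60 ± 0.28. Of the early stress and touch list 15 of 19 members (16 adjusted over the list alone) rose (adjusted p = 2.14e-07, adjusted p = 0.235 with an estimated correlation), among them WRKY40 (AT1G80840) (3.55 ± 0.21) and the cell wall enzyme TCH4 (AT5G57560) (2.48 ± 0.20). The ethylene list split into 7 higher and 7 lower of 17, the same adjusted over the list alone, with the synthase ACS6 (AT4G11280) at 2.32 ± 0.31 and the oxidase ACO1 (AT2G19590) at -1.85 ± 0.19 (adjusted p = 0.957). So did the unfolded protein response list, with 5 higher and 8 lower of 16, the same adjusted over the list alone (adjusted p = 0.864): BZIP60 (AT1G42990) and NAC062 (AT3G49530), its regulators, rose by 1.34 ± 0.08 and 1.64 ± 0.11. Among hypoxia genes HRE2 rose by 5.92 ± 0.39 and PDC1 (AT4G33070), of fermentation, by 2.35 ± 0.14, while HRE1 (AT1G72360) fell by 2.83 on the log2 scale; the list did not pass (adjusted p = 0.346). Of the root tissue list 12 of 18 members (12 adjusted over the list alone) fell (adjusted p = 0.00106, adjusted p = 0.235 with an estimated correlation), among them the root hair genes RSL4 (AT1G27740) (-2.87 ± 0.40), EXPA18 (AT1G62980) (-2.95 ± 0.39) and PRP3 (AT3G62680) (-3.25 ± 0.63). AT5G40590, annotated with a cysteine and histidine-rich domain, changed by -5.64 ± 0.41. In all, 4403 genes were higher and 4291 lower among 20144, 1683 and 1404 by 2-fold or more, and 49.2% did not overlap (chance 10%). The share of higher genes was 50.6%, and 38.6% with the authors' scaling factors. Of the 2409 genes higher in shoots at 1 h among those tested in both organs, 1768 were also higher in roots, where independent lists of these sizes would share 543, and 77 were lower there.

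After 3 h abscisic acid and starvation genes rose in roots. BGLU30 rose by 6.5 ± 0.26 (1712 ± 76.1 against 19.1 ± 2.93, n = 3 and 2, adjusted p = 4.2e-19) and CYP81D8 (AT4G37370), a cytochrome P450, by 5.46 ± 0.37. Of the abscisic acid and drought list 18 of 22 members (18 adjusted over the list alone) rose and 1 fell, median 2.02 (adjusted p = 2.57e-09, adjusted p = 0.0223 with an estimated correlation), with HAI1 at 5.38 ± 0.35 and CYP707A1 (AT4G19230), which breaks down the hormone, at 3.95 ± 0.30. All 12 carbon starvation and darkness genes rose (12 adjusted over the list alone), median 1.78 (adjusted p = 2.49e-10, adjusted p = 0.104 with an estimated correlation), with the asparagine synthetase DIN6 (AT3G47340) at 4.86 ± 0.43, the proline dehydrogenase PRODH1 (AT3G30775) at 2.99 ± 0.26 and SEN1 at 2.25 ± 0.36. Detoxification genes rose in 41 of 47 members (41 adjusted over the list alone), median 2.65 (adjusted p = 1.74e-34, adjusted p = 0.000345 with an estimated correlation). All 11 sulfate genes rose (11 adjusted over the list alone), median 2.04 (adjusted p = 6.03e-12, adjusted p = 0.0114 with an estimated correlation), with LSU1 at 4.15 ± 0.28 and APR2 (AT1G62180) and APR3 at 2.50 ± 0.17 and 2.48 ± 0.18.

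Genes of the root tissue and cell cycle lists fell in roots at 3 h. Of the root tissue list 12 of 18 members (12 adjusted over the list alone) fell and none rose, median -2.65 (adjusted p = 9.49e-05, adjusted p = 0.131 with an estimated correlation). FRO2, the iron reductase of the root surface, changed by -6.65 ± 1.21. Of the cell cycle list 26 of 30 members (26 adjusted over the list alone) fell (adjusted p = 4.87e-07, adjusted p = 0.101 with an estimated correlation). In the auxin list 6 of 19 rose and 7 fell (6 and 8 adjusted over the list alone), with GH3.3 at 5.03 ± 0.40, the influx carrier LAX3 (AT1G77690) at -2.36 ± 0.17 and the repressor IAA3 (AT1G04240) at -1.79 ± 0.27 (adjusted p = 0.809). In the DNA damage list 1 of 18 rose and 8 fell (1 and 9 adjusted over the list alone), with NAC044 at 2.01 ± 0.55 and the kinase WEE1 (AT1G02970) at -1.42 ± 0.41 (adjusted p = 0.103). Of isoprenoid genes 6 of 15 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.685): HDR (AT4G34350) and HMG1 (AT1G76490) rose by 1.63 ± 0.14 and 0.96 ± 0.08, and CMK (AT2G26930) changed by -1.30 ± 0.30. In clock genes these libraries lay 1.26 from their own ethanol group and 0.91 from the ethanol group of 1 h. In all, 4392 genes were higher and 5160 lower, 1871 and 2641 by 2-fold or more, and 47.8% did not overlap (chance 10%). The median of all genes lay at -0.10. The count of 9552 was 5360 without ethanol replicate 3, where the calls of NAC044 and WEE1 were lost.

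Division and microtubule genes fell in roots at 6 h. Of the cell cycle list 27 of 30 members (28 adjusted over the list alone) fell, median -1.43 (adjusted p = 1.03e-09, adjusted p = 0.0346 with an estimated correlation): CDC20.1 (AT4G33270) and CYCB1;1 (AT4G37490), which act in mitosis, changed by -2.90 ± 0.18 (8.57 ± 0.778 against 70.2 ± 13.8, adjusted p = 1.48e-16) and -2.63 ± 0.28, and the cytokinesis syntaxin KNOLLE (AT1G08560) by -2.33 ± 0.23. Of the microtubule list 17 of 20 members (17 adjusted over the list alone) fell, median -0.77 (adjusted p = 1.23e-11, adjusted p = 0.0228 with an estimated correlation), with TUB1 at -2.16 ± 0.15, TUB5 at -1.98 ± 0.12, TUA4 (AT1G04820) at -1.45 ± 0.08 and MAP65-3 (AT5G51600), of the division plane, at -2.12 ± 0.21. The extensin EXT13 (AT5G35190) changed by -7.55 ± 1.35. AT1G60750, annotated as an NAD(P)-linked oxidoreductase, rose by 7.02 ± 0.20 and ABCG40 by 6.35 ± 0.37. Detoxification genes rose in 41 of 47 members (42 adjusted over the list alone) (adjusted p = 2.63e-35, adjusted p = 0.000345 with an estimated correlation), oxidative stress genes in 16 of 22 members (17 adjusted over the list alone) (adjusted p = 1.5e-08, adjusted p = 0.00567 with an estimated correlation) and flavonoid genes in 13 of 15 members (13 adjusted over the list alone) (adjusted p = 1.78e-05, adjusted p = 0.168 with an estimated correlation), with F3H at 2.2 ± 0.32 and CHI (AT3G55120) at 2.2 ± 0.38. In all, 4616 genes were higher and 5212 lower, 1404 and 1863 by 2-fold or more, and 53.1% did not overlap (chance 10%). The call of CHI was lost in a fit of the compared groups alone.

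At 12 h detoxification genes rose, and the iron uptake genes IRT1 and FRO2 fell, in roots. AT5G16980, annotated as a zinc-binding dehydrogenase, rose by 6.88 ± 0.42 (39.6 ± 1.95 against 0.326 ± 0.206, adjusted p = 4.12e-16), the aldo-keto reductase AKR4C9 (AT2G37770) by 5.79 ± 0.39 and DOGT1 by 6.10 ± 0.44. The iron transporter IRT1 (AT4G19690) fell by 7.61 on the log2 scale (2.34 ± 2.03 against 448 ± 136) and FRO2 by 6.80. Of the detoxification list 39 of 47 members (40 adjusted over the list alone) rose (adjusted p = 1.91e-37, adjusted p = 0.000345 with an estimated correlation), of the sulfate list 10 of 11 members (11 adjusted over the list alone) (adjusted p = 1.78e-11, adjusted p = 0.0119 with an estimated correlation) and of the oxidative stress list 15 of 22 members (16 adjusted over the list alone) (adjusted p = 2.08e-07, adjusted p = 0.00882 with an estimated correlation). Clock genes differed here too: LHY fell by 4.11 on the log2 scale, and PRR5 (AT5G24470) and ELF4 rose by 3.6 ± 0.21 and 3.16 ± 0.21. These libraries lay 1.97 in clock genes from their own ethanol group and 0.57 from the ethanol group of 3 h. In all, 3526 genes were higher and 3727 lower, 910 and 1114 by 2-fold or more, and 44.6% did not overlap (chance 10%).

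After 24 h jasmonate genes were higher and salicylic acid genes lower in roots. Of the jasmonate list 17 of 23 members (17 adjusted over the list alone) rose and 0 fell, median 1.35 (adjusted p = 5.79e-10, adjusted p = 0.0113 with an estimated correlation). JRG21 (AT3G55970), a jasmonate-regulated dioxygenase, rose by 6.37 ± 0.58 (16.5 ± 8.39 against 0.124 ± 0.0682, adjusted p = 1.15e-10) and CYP94B3 by 2.14 ± 0.17. Of the salicylic acid list 12 of 18 members (12 adjusted over the list alone) fell (adjusted p = 0.000541, adjusted p = 0.169 with an estimated correlation), with WRKY54 (AT2G40750) at -3.55 ± 0.53, FMO1 (AT1G19250), of systemic resistance, at -3.07 ± 0.45 and PBS3 (AT5G13320), which acts in salicylic acid synthesis, at -3.51 ± 0.56. FRO2 changed by -7.50 ± 1.51, and IRT1, at 274 ± 121 with ethanol, was listed at the floor in all 3 citral libraries. Of the detoxification list 35 of 47 members (35 adjusted over the list alone) rose and 7 fell (adjusted p = 5.41e-20, adjusted p = 0.00746 with an estimated correlation), with AT5G16980 at 6.29 ± 0.41 and DOGT1 at 6.03 ± 0.50. Of the photosynthesis list, which marks shoot tissue, 13 of 29 members (13 adjusted over the list alone) were higher in these roots (adjusted p = 0.00832, adjusted p = 0.711 with an estimated correlation), with GAPB (AT1G42970) at 1.22 ± 0.18 and LHCB4.1 (AT5G01530) at 1.05 ± 0.16. The light-harvesting gene LHCB1.1 went the other way, from 0.91 to 1.45 CPM over libraries with citral and 2.44 to 12.4 with ethanol. The clock genes lay 2.18 from their own ethanol group and 0.62 from the ethanol group of 3 h. In all, 3939 genes were higher and 3814 lower, 1039 and 1256 by 2-fold or more, and 45.5% did not overlap (chance 10%). The share of higher genes was 50.8%, and 39.2% with the authors' scaling factors. Ethanol replicates 1 and 2 differed by 1.29 times the sampling noise in variance and replicate 3 from them by 23.46 and 22.21 times, and their library weights in the fit were 2.363, 1.931 and 0.154. The count of 7753 was 3919 and 4082 without ethanol replicates 1 and 2, where the call of LHCB4.1 was lost, as was that of GAPB with limma-trend.

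The title of the series names single-strand DNA-binding proteins, and 22 genes of this class were followed in every comparison. RPA2A (AT2G24490), a subunit of replication protein A, rose by 4.35 ± 0.23 in shoots at 1 h (111 ± 31.5 against 5.40 ± 0.251, adjusted p = 5.99e-16) and by 3.02 ± 0.08 in roots (126 ± 5.96 against 15.73 ± 0.318, adjusted p = 2.28e-28). The rise was 2.83 ± 0.18 in shoots and 2.42 ± 0.14 in roots at 3 h, 1.06 ± 0.23 and 1.34 ± 0.11 at 6 h, and 1.09 ± 0.11 in roots at 12 h. Other subunits of replication protein A were lower at 3 h: RPA1B (AT5G08020) by -2.12 ± 0.36 and RPA1D (AT5G61000) by -1.70 ± 0.27 in roots, RPA3A (AT3G52630) by -1.49 ± 0.33 in shoots and -1.31 ± 0.36 in roots, and RPA1D by -1.05 ± 0.27 in shoots. RPA1B was at -1.41 ± 0.24 in roots at 6 h. OSB3 (AT5G44785), an organelle DNA-binding protein, changed by -1.04 ± 0.12 and RPA1A (AT2G06510) by 0.38 ± 0.15 in shoots at 3 h. Of the 22 members 1 rose and 0 fell in shoots at 1 h, 2 rose and 9 fell at 3 h, and 1 rose and 4 fell in roots at 1 h and 2 and 8 at 6 h, the same numbers adjusted over the list alone. The list passed in none of the 10 citral comparisons of the limma set test, with adjusted p = 0.051 as the lowest (shoots, 24 h). With limma-trend at a pseudocount of 0.5 the calls of RPA3A in both organs, RPA1D and OSB3 in shoots at 3 h and RPA2A in shoots at 6 h were lost, and that of RPA1A was lost without library weights and with the authors' scaling factors. The upstream gene FZF (AT2G24500), looked at only after its values were seen, shares 173 bases with RPA2A on the same strand. It rose by 3.66 ± 0.13 in shoots at 1 h (519 ± 82.7 against 41.1 ± 1.80), by 2.97 ± 0.06 in roots (462 ± 1.98 against 59.3 ± 1.72), and by 2.91 ± 0.11 and 2.81 ± 0.10 at 3 h. RPA2A stood at 21.4% of FZF with citral and 13.1% with ethanol in shoots at 1 h, and at 27.4% and 26.5% in roots. At 3 h this share was lower with citral: in shoots RPA2A stood at 70.3 ± 9.26 and FZF at 386 ± 27.3 with citral and at 10.15 ± 2.35 and 51.4 ± 1.48 with ethanol, and in roots the share was 26.7% and 34.3%. At 6 h it was 13.5% and 30.9% in shoots and 25.2% and 31.8% in roots.

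**Figure D3:**
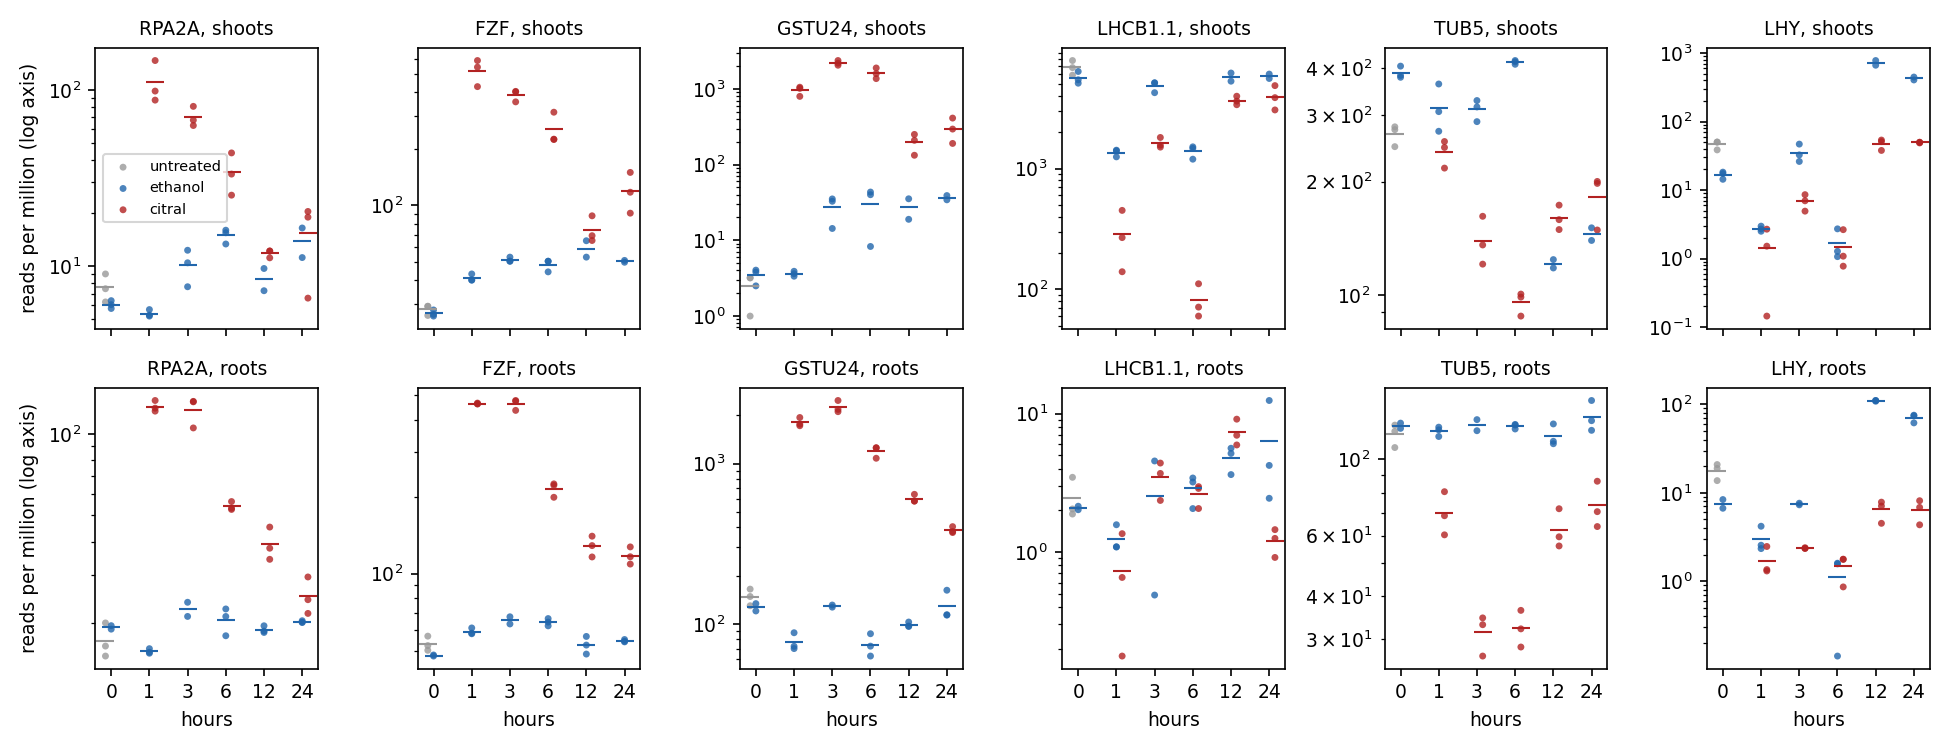
CPM on a log axis against hours for 6 genes in shoots (top) and roots (bottom); each point is 1 library of 0.5 M reads or more, bars are group means, and colours mark untreated, ethanol and citral plants. RPA2A at 1 h stands at 110.9 with citral and 5.40 with ethanol in shoots, with FZF moving alongside it.

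Shoots and roots were compared directly in 1 fit of all 72 libraries, which tested the difference of their citral responses over the 5 times. SULTR2;1 (AT5G10180), a low-affinity sulfate transporter, was on average 2.22 higher on the log2 scale in the root response than in the shoot response, the expansin-like gene EXLB1 (AT4G17030) 2.28, AT2G43500 2.08, the auxin efflux carrier PIN3 (AT1G70940) 1.80 and the repressor IAA13 (AT2G33310) 1.38. The mean difference was -1.59 for the glutathione transferase GSTU19 (AT1G78380), -1.53 for AT4G19880, annotated in the same family, -1.64 for the histidine kinase HK1 (AT2G17820), -1.72 for the protease inhibitor AT1G17860 and -1.80 for the receptor kinase CRK3/AT1G70530. Adjusted p of these 10 genes ranged from 2.93e-26 (AT4G19880) to 7.39e-22 (IAA13). The auxin list was on balance higher in the root response (median 0.83, adjusted p = 1.91e-05, adjusted p = 0.0446 with an estimated correlation). Of 21112 genes tested, 13471 (63.8%) differed, 6512 with a mean above 0 and 6959 below. The count was 7271 without library weights, and 8531, 6383 and 8276 without replicate 1, 2 or 3 of every group.

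Ethanol was compared with no treatment at 0 h. Clock genes of these groups lay 1.02 apart in shoots and 0.90 in roots, with LHY at 16.7 ± 2.05 and CCA1 at 49.5 ± 3.52 in ethanol shoots and 46.4 ± 6.72 and 130.5 ± 11.1 in untreated ones. In shoots ERF105 rose by 5.15 ± 0.47 (231 ± 76.9 against 5.76 ± 2.19, adjusted p = 2.86e-08), its relative ERF104 (AT5G61600) by 4.71 ± 0.36 and CYP707A3 (AT5G45340), which breaks down abscisic acid, by 4.60 ± 0.62, while SDI1 fell by 4.94 on the log2 scale. Of the early stress and touch list 15 of 19 members (16 adjusted over the list alone) rose, median 2.57 (adjusted p = 9.02e-14, adjusted p = 0.162 with an estimated correlation), with WRKY40 at 3.1 ± 0.69 and TCH4 at 1.75 ± 0.31. Of the sulfate list 8 of 11 members (8 adjusted over the list alone) fell (adjusted p = 1.7e-08, adjusted p = 0.137 with an estimated correlation). In the ethanol groups against untreated plants the touch list had a median of 3.23 in shoots at 1 h and -0.48 at 24 h. In all, 1814 genes were higher and 2553 lower, 424 and 399 by 2-fold or more, and 34.1% did not overlap (chance 10%). The count of 4367 was 527 without library weights and 1721 without ethanol replicate 3, and the call of WRKY40 was lost with limma-trend.

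In roots at 0 h the jasmonate list stood apart, with 19 of 23 members (20 adjusted over the list alone) rising and 0 falling, median 2.17 (adjusted p = 2.89e-22, adjusted p = 9.95e-05 with an estimated correlation). JAZ8 rose by 3.75 ± 0.59 and CYP94B3 by 2.58 ± 0.13 (66.2 ± 6.79 against 11.5 ± 2.17, n = 2 and 3, adjusted p = 7.32e-19). RRTF1 rose by 6.07 ± 1.11, AT1G17345, annotated as auxin-responsive, by 5.50 ± 0.29 and AT1G76640, annotated as calcium-binding, by 5.36 ± 0.52. Of the touch list 10 of 19 members (12 adjusted over the list alone) rose (adjusted p = 5.89e-07, adjusted p = 0.319 with an estimated correlation), with WRKY40 at 3.61 ± 0.44 and TCH4 at 2.88 ± 0.24. In all, 3004 genes were higher and 2195 lower, 1129 and 363 by 2-fold or more, and 32.2% did not overlap (chance 10%). The share of higher genes was 57.8%, 44.8% with the authors' scaling factors and 45.2% after quantile normalization. The count of 5199 was 1854 and 1980 without ethanol replicates 2 and 3.

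**Figure D4:**
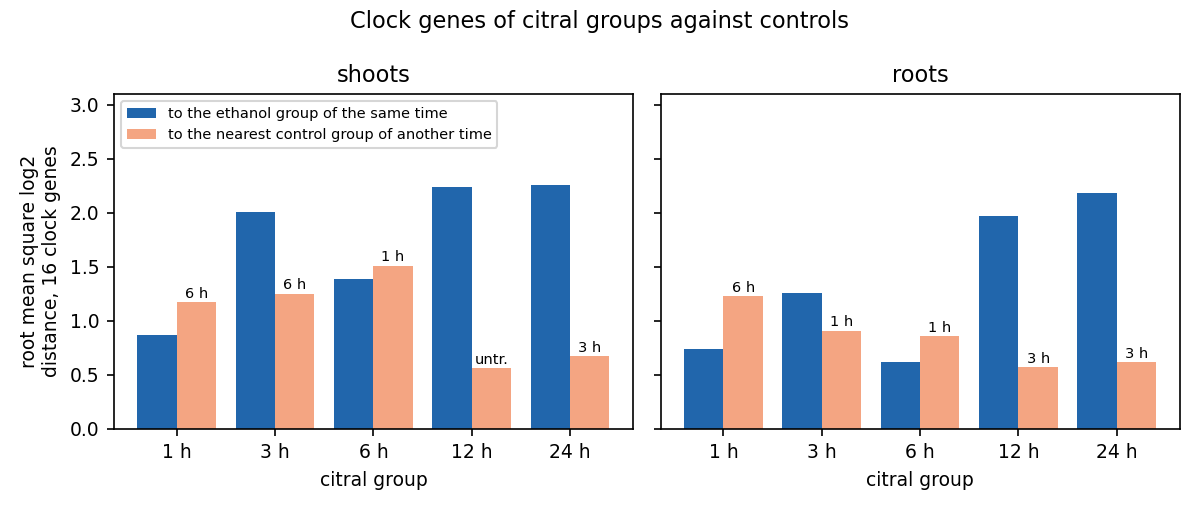
Root mean square log2 distance over 16 clock genes from each citral group to the ethanol group of the same time and to the nearest control group of another time, named above the bar by its hours, with "untr." for untreated at 0 h. At 3, 12 and 24 h the other group is nearer in both organs, 0.56 against 2.24 in shoots at 12 h.

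Genes that overlap others in the annotation are uncertain, since the sources used here do not say that counting used strand. Among genes named here these are RPA2A, FZF, RPA1B, RPA3A, OSB3, CYP81D11, AT5G22140, GPX6, HSP17.4, WRKY40, WRKY53, ERF105, RRTF1, HRE1, LHCB2.3, LHCB3, IAA3, IAA13, TUB1, TUA2, CYCA2;3, CYCD3;1, CDC6, KNOLLE, CHS, F3H, BCAT2, DIN6, LUX, RVE1, MCT, FPS1, IPP2, CMK, APR2, APR3, SERAT2;1, EXPA18, CASP1 and AT1G17860. LHCB1.1, TUA2 and TUA4 have close copies that may share reads. The authors' scaling factors moved the median log2 change of all genes to between -0.23 and -0.02. For the lists that passed with citral, medians had the same sign with these factors, after quantile normalization and after centring. With 1 common factor for all libraries, as the deposited values stand, it lay between -2.61 (roots, 24 h) and 0.48 (shoots, 24 h), and the share of higher genes was 0.732%, 0.605%, 1.72%, 11.5% and 100% in shoots from 1 to 24 h, and 0.317%, 75.2%, 10%, 0.643% and 0.0499% in roots. It was 75.6% and 68.0% in shoots and roots at 0 h, and 34.9% of the genes that differed between the organs.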

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

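The set test on the mean difference between organs and the splits without library weights were chosen after the results were seen.

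Responses of gene lists to citral that differed between organs were found by the limma set test on the mean difference over the 5 times, root minus shoot. Photosynthesis genes had a median of 0.94 (adjusted p = 1.64e-16, adjusted p = 0.133 with an estimated correlation), and phenylpropanoid and flavonoid genes 0.96 (0.00159 and 0.469). Auxin genes had a median of 0.83 (adjusted p = 1.91e-05), the one list of the 22 that also passed with an estimated correlation (adjusted p = 0.0446). Abscisic acid and drought genes had a median of 0.66 (0.0392, and 0.547 with an estimated correlation) and jasmonate genes 0.38 (0.0209 and 0.651). Detoxification genes had a median of -0.57 (8.93e-07, and 0.469 with an estimated correlation), heat shock and protein folding genes -0.71 (0.0209 and 0.651) and unfolded protein response genes -0.35 (0.00129 and 0.547). Sulfate assimilation and glutathione genes had a median of -0.41 (0.0392 and 0.651), microtubule genes -0.12 (0.0445 and 0.651) and root tissue genes -1.38 (0.0286 and 0.547). A gene of low level in an organ has little room to fall there. With ethanol at 6 h LHCB1.1 ran from 2.06 to 3.42 CPM in roots and 1194 to 1510 in shoots, and the root genes COBL9 and CASP1 stood lower in shoots. For the photosynthesis and root tissue lists the difference was not separated from the level of expression. The lists of single-stranded DNA-binding proteins, oxidative stress, salicylic acid, early stress and touch, ethylene, cell cycle and DNA replication, DNA damage response, hypoxia, carbon starvation and darkness, circadian clock and isoprenoid synthesis did not pass.

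Of single genes, the 5 with the smallest p in each direction of the limma F test were more positive in roots for the sulfate transporter gene SULTR2;1 (2.22), EXLB1 (2.28), AT2G43500 (2.08), the auxin efflux carrier gene PIN3 (1.80) and IAA13 (1.38). They were more negative in roots for GSTU19 (-1.59) and AT4G19880 (-1.53), both annotated as glutathione transferases, HK1 (-1.64), AT1G17860 (-1.72) and CRK3/AT1G70530 (-1.80).

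The count of 13471 genes that differed between the organs was reached or passed by 8 of 40 drawn splits, the real one included, and the highest of the others gave 15317, so chance was not excluded for this count. Without library weights the real split gave 7271 genes and the highest of the others 2808, with 1 of the 40 as large.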

How the results depend on the processing

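Tests chosen after the data were seen were limma-trend per library at 0.5 CPM, the fit without library weights, the authors' scaling factors, other values at the floor, leaving out the 4 libraries under 0.5 M and thinning. The test with 1 common factor was the one first planned and was kept as an alternative. No paired analysis was possible because the labels carry no replicate numbers. Of 179 changes of named genes, none reversed in the alternatives run per gene (0), which left out the test with 1 common factor. With these alternatives 3632 comparisons gave the same call and 122 lost it. Losses by setting were 20, 18 and 15 with limma-trend at pseudocounts of 0.1, 0.5 and 2, 15 with limma without weights, trend or robust prior, 6 after thinning, 5 with the compared groups alone, 5 without library weights, 1 with the authors' scaling factors and 37 with 1 replicate left out. The 13 counts of genes stayed within 1.5 times with no filter, a filter of 5 CPM, the compared groups alone, quantile normalization, centring, the authors' scaling factors, the floor as 0 or 1 read and without the 4 shallow libraries. Depth limits low genes most, since 1 read in the smallest library stands for over 5 CPM. Where a count moved, the cause was not tested, except that thinning and leaving out libraries test fewer reads by construction.

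Counts that moved are given for shoots at 1, 3, 6, 12 and 24 h, roots at the same times, shoots and roots at 0 h, and the difference between organs, leaving out those within 1.5 times. With limma-trend at 0.1 they were 763, 2638, 2479 and 2182 in shoots at 1, 3, 6 and 24 h, 5116, 6327, 3840 and 4701 in roots at 1, 6, 12 and 24 h, 137 and 2661 at 0 h and 4664 between organs. At 2 they were, in this order, 971, 3037, 2791, 2684, 5220, 6507, 4039, 4920, 215, 2924 and 6454. At 0.5 they were 819, 2780, 2560, 2380, 5168, 6386, 3919, 4821, 154, 2783 and 5239. Limma without weights, trend or robust prior gave 957, 3136, 2899 and 2664 in shoots, 5409, 3923 and 4939 in roots at 1, 12 and 24 h, 177 and 2721 at 0 h and 5872 between organs. With 1 common factor, as first planned, they were 6694, 3596, 157 and 43 in shoots at 1, 6, 12 and 24 h, 15446, 137, 420, 1710 and 18022 in roots from 1 to 24 h, 45 and 25 at 0 h and 3835 between organs. Without library weights they were 1526, 4579, 3998, 3279 and 2693 in shoots from 1 to 24 h, 527 in shoots at 0 h and 7271 between organs. Thinned to 1.5 M reads they were 2427, 6489, 5370 and 3843 in shoots at 1, 3, 6 and 12 h, 5109, 6457, 4106 and 4594 in roots at 1, 6, 12 and 24 h, 1154 and 2320 at 0 h and 8205 between organs.

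With each replicate left out in turn, the lone or paired libraries of a group being taken to vary like the other groups, counts in shoots ranged from 2578 to 3636 at 1 h, 7743 to 9514 at 3 h, 5873 to 7783 at 6 h, 798 to 7428 at 12 h and 3311 to 6818 at 24 h. In roots they ranged from 5912 to 8003 at 1 h, 5360 to 9494 at 3 h, 7916 to 9526 at 6 h, 5423 to 6971 at 12 h and 3919 to 7680 at 24 h. They ranged from 1721 to 3728 in shoots and 1854 to 5204 in roots at 0 h, and from 6383 to 8531 between organs. Counts moved over 1.5 times in shoots without citral replicate 3 at 1 h (2578), without ethanol replicate 1 (1015) or 3 (798) at 12 h, without citral replicate 2 (3411) or ethanol replicate 1 (3311) or 2 (3742) at 24 h and without ethanol replicate 3 (1721) at 0 h. In roots they did so without ethanol replicate 3 at 3 h (5360), without ethanol replicate 1 (3919) or 2 (4082) at 24 h, and without ethanol replicate 2 (1854) or 3 (1980) at 0 h. Between organs each of the replicates moved the count (8531, 6383 and 8276).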

Other observations

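The gene families, the comparison of 24 h citral with 0 h ethanol, the clock tests, the test of a shared run, the RPA2A tests and the splits without library weights were chosen after results were seen; the depth test and the splits were written before.

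Among 11 gene families, subunits of the proteasome, which degrades proteins, rose together at 3 and 6 h, and in shoots at 12 h. In shoots 34 of 36 rose at 3 h (median 0.55, adjusted p = 5.87e-13, adjusted p = 0.111 with an estimated correlation) and 35 at 6 h (median 1.00, adjusted p = 9.23e-25, adjusted p = 0.0397 with an estimated correlation), and 26 rose and none fell at 12 h (median 0.46, adjusted p = 9.79e-09 and 0.173). In roots 33 rose at 3 h (median 0.72, adjusted p = 9.65e-17 and 0.0147 with an estimated correlation) and 35 at 6 h, where 1 fell (median 0.78, adjusted p = 4.24e-23 and 0.00472). At 1 h in roots 15 fell and 3 rose (median -0.16, adjusted p = 0.0193 and 0.413), and at 24 h there 8 were lower and 4 higher (adjusted p = 0.182). Aquaporins, which let water pass membranes, fell in both organs: in roots 23 of 26 at 12 h (median -0.75, adjusted p = 5.87e-13 and 0.0397) and 21 at 24 h (median -0.90, adjusted p = 2.44e-14 and 0.0375), and in shoots 17 of 26 at 3 h (median -1.16, adjusted p = 3.48e-05 and 0.148) and 16 at 6 h (median -0.88, adjusted p = 2.03e-06 and 0.0982). Of the xyloglucan endotransglucosylases, which remodel cell walls, 18 of 24 fell in roots at 3 h (median -2.03, adjusted p = 3.78e-05, and 0.0600 with an estimated correlation) and 18 at 12 h (median -1.16, adjusted p = 9.16e-07 and 0.0375), and 14 of 22 fell in shoots at 3 h (median -1.52, adjusted p = 0.000723 and 0.111). Genes of glucosinolate synthesis, a defence pathway, fell at 3 h in shoots (22 of 26, median -1.96, adjusted p = 9.16e-07 and 0.263) and roots (21 of 23, median -1.68, adjusted p = 2.58e-11 and 0.0574), and 19 of 23 rose in roots at 24 h (median 0.53, adjusted p = 9.44e-08 and 0.111). Cytosolic ribosomal protein genes fell in shoots at 24 h (36 of 58, median -0.69, adjusted p = 9.92e-12 and 0.0982), and 12 of 18 iron uptake genes fell there (median -2.01, adjusted p = 0.000146 and 0.154). The root genes COBL9 and CASP1 stood at 2.63 and 4.91 CPM in ethanol shoots of 24 h and at 0.584 and 2.52 with citral, and root tissue carried into these control shoots was not tested as a cause. The medians given here had the same sign with the authors' scaling factors, after quantile normalization and after centring.

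Citral libraries of 24 h were also set against ethanol libraries of 0 h. Of the 6489 genes called at 24 h in shoots, 2795 (43.1%) were called in the same direction and 719 in the opposite one, and of 7753 in roots 3781 (48.8%) and 398. In all, 7872 genes in shoots and 7135 in roots were called against 0 h. Both comparisons use the same citral libraries, which favours a shared direction, so the second is not independent of the first. Against 0 h, 40 of 46 detoxification genes were higher in shoots and 35 of 47 in roots, 11 and 10 of 11 sulfate assimilation genes, and 21 of 29 photosynthesis genes in roots. In roots 17 of 23 jasmonate genes were lower against 0 h and 3 higher (median -1.16), and 15 of 25 heat shock genes were lower (median -0.96), while in shoots 23 of 25 heat shock genes were higher and 1 lower (median 2.90). Both lists were raised in the root reference, where 19 of the 23 (median 2.17, adjusted p = 2.89e-22 and 9.95e-05 with an estimated correlation) and 11 of the 25 (median 0.53, adjusted p = 0.000809 and 0.415) were higher than in untreated roots. In shoots 5 of 12 carbon starvation genes were higher against 0 h and 1 lower (median 0.45), and in that reference 6 were higher and 2 lower than in untreated shoots (median 0.61, adjusted p = 0.0341 and 0.620).

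Clock genes differed between citral and ethanol libraries at 12 and 24 h. The hours given by the labels are argued against by the ethanol controls, since the ethanol groups of 0 and 24 h lay at least 2.91 times as far apart as the 0 h group and its nearest ethanol group; untreated plants of 0 h lay 1.48 in shoots and 1.25 in roots from the ethanol groups of 24 h, against 0.94 and 0.79 from their nearest. Ethanol groups of 24 h lay nearest to those of 12 h, at 0.83 in shoots and 0.52 in roots. In shoots the ethanol group of 1 h lay 0.76 from that of 6 h and 2.56 from that of 3 h. Citral groups of 24 h lay 1.16 in shoots and 0.68 in roots from the ethanol groups of 0 h. In both organs and at both times the citral group lay nearer to a control of another hour, at no more than 0.30 of the distance to its own control. A harvest at another hour than the controls may thus account for the pattern, and which groups were out of place was not settled. A change of the clock by citral was left undecided, with distances at 12 and 24 h that were 1.32 times those at 3 and 6 h in shoots and 2.21 times in roots.

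Many genes changed by 2-fold or more at 1 to 6 h, when citral libraries were also shallower than most of their controls. Root ethanol 3 h replicate 1 (0.183 M reads) and 6 h replicate 1 (3.328 M) were shallower than the root citral libraries of their time. Unequal depth as the cause of the direction of these 2-fold changes is argued against by thinning, without the 4 libraries under 0.5 M reads. At equal depth at least 98.7% of the genes still measured had the same direction. From 985 of 1367 (shoots, 1 h) to 3652 of 4512 (roots, 3 h) were still called. The genes were picked by their change in the same reads, which favours a kept direction, and sizes of change were not compared. Other differences between citral and control libraries are not reached by thinning. A run shared by the citral libraries, with the same effect at all times, is argued against as the whole cause by the change at 24 h. On median it was 0.43 of that at 3 h in shoots and 0.21 in roots. The genes were picked for their change at 3 h, which lowers this ratio by an amount not measured, and hours of harvest may differ too. The labels give no runs, so runs that differed between times are not reached, and a part from a shared run stays open. A response to citral is 1 hypothesis for changes beyond such effects of runs, found and tested on the same data. At 3 h the hour of harvest was not excluded.

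RPA2A rose at 1 and 3 h beside its overlapping neighbour FZF. A constant share of the reads of FZF (12.9%) left 28.4 to 53.2% of the rise, with every citral library above every ethanol library. The share was the lowest ratio of RPA2A to FZF among the groups, that of citral shoots at 24 h, and so came from the same data. The ratio reached 40.4% in ethanol roots at 0 h, and a share that varied between groups was not tested. Read-through past induced genes in general stays open: at 1 h downstream and upstream neighbours of induced genes were called higher in 30.3 and 38.1% of cases in shoots (a difference of -7.8 points, 95% interval -24.4 to 8.9, Fisher p = 0.384) and 34.0 and 45.7% in roots (-11.7 points, -27.0 to 3.6, p = 0.129), against 12.6 and 21.9% of all genes tested. Read-through from FZF alone stays open, because RPA2A as a percent of FZF was 1.63 times as high with citral as with ethanol in shoots at 1 h and 1.03 times in roots, and lower with citral at 3 h (26.7 against 34.3% in roots) and at 6 h (13.5 against 30.9% in shoots and 25.2 against 31.8% in roots). A rise of RPA2A itself may account for it as well.

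The 6 libraries of each comparison make 10 splits, too few for a share under 0.05, and the real split gave the most genes in each of the 12 comparisons (1 of 10 as large). The real and the highest other count in shoots were 4023 and 2251 at 1 h, 9804 and 8496 at 3 h, 8130 and 7783 at 6 h, 7435 and 6668 at 12 h and 6489 and 5861 at 24 h. In roots they were 8694 and 7008, 9552 and 8865, 9828 and 9116, 7253 and 5763, and 7753 and 6017 at the same times. At 0 h they were 4367 and 3077 in shoots and 5199 and 4756 in roots. Library weights were estimated anew in each split, and in the highest other split the moved libraries had mean weights of 0.108 to 0.419 against 0.957 to 1.904 for the rest. Without weights the real and highest other counts were 1526 and 12, 4579 and 0, 3998 and 0, 3279 and 1785, and 2693 and 39 in shoots from 1 to 24 h, and 7189 and 91, 9629 and 5266, 8413 and 2, 5511 and 264, and 5713 and 481 in roots. At 0 h they were 527 and 0 in shoots and 4391 and 1480 in roots.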
